A study of Homo sapiens with 9 samples.

How the data were processed

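Gene expression was measured in MV4-11, an established human acute myeloid leukaemia cell line, after 24 h with the vehicle DMSO, with JPX-0700 or with JPX-0750. The series title calls the compounds dual degraders of the transcription factors STAT3 and STAT5. Each group had 3 libraries, 9 in all, and whether the replicates of a group were separate cultures is not given in the sources used here, so every p-value measures the spread between these samples. The dose is not given in the labels. Whether DMSO and treated libraries were prepared together, and the quality of their RNA, are not given in the sources used here. Per the labels, total RNA was isolated with a column kit, and libraries were made with the QuantSeq kit, which reads the 3′ end of polyadenylated RNA. The protocol text names no molecular identifiers, so reads are not independent molecules, and counting intervals and floors cover counting error only.

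The submitters' processing notes name FastQC 0.11.9, STAR 2.4.2a, SAMtools 1.4, featureCounts 2.0.3, DESeq2 without a version and the genome build GRCh38. The strand that was counted, the annotation and the handling of reads that map to several places are not given in the sources used here. The table the authors deposited holds normalised counts of 26929 genes, named by symbol, in 9 columns, written with a decimal comma. Within each library 100% of the values above 0 were whole multiples of the smallest one, at a tolerance of 1e-06. The values were therefore read as gene counts divided by 1 factor per library, and whole reads were recovered by dividing by that smallest value. Recovered totals ran from 726043 to 6305586 reads per library, and 1 read was worth 0.383 to 4.61 normalised counts. Symbols were matched to the RefSeq annotation of GRCh38, 24159 by current symbol and 1442 by a synonym, and 1328 found no match. That annotation gave coordinates, overlaps and gene classes.

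Tests used log2(normalised count + 1). Genes with a mean of at least 5 over the 9 libraries were tested, which kept 12301 and left out 14628, among them 8846 with no value above 0. limma 3.58.1 in R 4.3.3 fitted a mean per group over all 9 libraries with 6 residual degrees of freedom, with moderated variances that follow a trend on expression. Comparisons were JPX-0700 with DMSO, JPX-0750 with DMSO and JPX-0750 with JPX-0700, each two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold, and "rose", "fell" and "changed" refer to it. Adding 1 before the logarithm makes folds of weakly expressed genes smaller than the ratio of their means. For genes with at most 3 reads in a group the ratio of reads per scaled depth is given with its exact 95% counting interval, and for genes with 0 reads a bound from a floor of 3 reads over the group. Genes called in both compounds were counted and compared with 20 simulated sets of unchanged groups that shared the DMSO libraries, with noise drawn independently for each gene. Read classes and library shares were compared with two-sided exact permutation tests, for which 3 against 3 libraries allow no p below 0.1.

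For groups of genes, 33 lists were fixed, of which 32 had a tested member. They were STAT5 target genes, STAT3 target genes, STAT and JAK signalling components, negative regulators of cytokine signalling, type I interferon response, MHC class II and antigen presentation, G1/S and DNA replication, G2/M and mitosis, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, ATF4 amino acid response, ER chaperones and unfolded protein response, NRF2 antioxidant response, heat shock response, metallothioneins and metal response, proteasome subunits, p53 targets, BCL2 family, cholesterol biosynthesis, fatty acid synthesis, nuclear oxidative phosphorylation genes, glycolysis and hypoxia response, granule and progenitor genes, monocyte and macrophage genes, MLL fusion and HOXA programme, immediate early and ERK feedback genes, NF-kB targets and cytokines, lysosome and autophagy, and markers of T and NK, of B and plasma, of erythroid and megakaryocyte, and of epithelial and fibroblast cells. The table held 0 of the mitochondrially encoded mRNAs, the remaining list. Lists were tested against all other genes with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Beside these, fry tested each list for a net rise or fall, without comparing it with other genes. Its mixed form, which allows members to move in either direction, is given only where named. List members were counted over all genes tested and adjusted over the list alone.

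Genes were named by a rule. It takes STAT3, STAT5A and STAT5B; per compound the 6 genes with the highest and the 6 with the lowest log2 fold change past the threshold, with a mean of at least 20 over the 6 libraries and groups that do not overlap, passing over clone names, uncharacterised loci, pseudogenes of ribosomal proteins and of mitochondrial genes, and XIST and Y-linked genes; up to 4 members past the threshold of each called list or of a list with at least 3 members past it; up to 4 members of the STAT3 and STAT5 target lists, whether past the threshold or not; and, by the first of these rules with 5 per direction, genes differing between the compounds. Other genes are marked as chosen after their values were seen. The tests, the lists, the naming rule and the first set of alternatives were fixed before the data were examined.

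Those alternatives were a pseudocount of 0.5 or 5, no filter or a mean of at least 50, total-sum scaling, quantile normalization or TMM scaling with trims of 0.3 and 0.05, only the 2 groups compared, variances without the trend, the replicate number as a block, each library left out in turn, a log2 change of at least 1, and the other set tests. Added after seeing the data were fits without the 3 libraries with the fewest detected genes of their groups, voom on the recovered reads, thinning of every library to 726043 reads, the leaving out of structured noncoding RNAs, and the block with the JPX-0700 and JPX-0750 libraries alone. Structured noncoding RNAs were defined after seeing the data as 8 annotation classes (small nuclear, nucleolar, cytoplasmic, Y, vault, RNase P, RNase MRP and telomerase RNA) and RN7SK, 505 genes in the table and 261 tested. The 58 replication-dependent histone genes were taken by symbol.

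Replicate numbers were checked for pairing by correlating each library's deviations from its group mean. DMSO and treated libraries of the same number gave correlations from -0.143 to -0.0436, so they were not paired. JPX-0700 and JPX-0750 libraries of the same number gave 0.129, 0.171 and 0.190, so the block was tried for that comparison, although JPX-0700 replicate 2 with JPX-0750 replicate 1 gave 0.153. The test was tried on simulated data with 50 genes raised or lowered at each fold. These genes had a mean of at least 20, and no outlying libraries were simulated. The JPX-0700 comparison recovered 20% of the genes changed 4-fold, 42% at 8-fold, 58% at 16-fold and 86% at 64-fold, with 4 false calls of 107. The JPX-0750 comparison recovered 26%, 52%, 68% and 86%, with 1 false call of 117, and the comparison of the compounds 32%, 56%, 68% and 80%, with 5 of 123. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Raw reads, protein data and the lymphoma cells named in the series title were not analysed here. Some genes that the naming rule gives are not reported here.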

Results

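Messenger RNA 3′ ends were counted in 9 libraries of the acute myeloid leukaemia line MV4-11 after 24 h with DMSO, JPX-0700 or JPX-0750, with 3 libraries per group. DMSO libraries held 2701317, 6305586 and 4035371 reads on genes. JPX-0700 libraries held 739418, 891990 and 1852375 reads, and JPX-0750 libraries held 1069328, 726043 and 1941860. Genes with at least 1 read numbered 9816, 13068 and 13711 with DMSO, 13940, 14228 and 10027 with JPX-0700, and 14616, 13647 and 10407 with JPX-0750. Thus 1 library of each group (DMSO replicate 1, JPX-0700 replicate 3 and JPX-0750 replicate 3) detected fewer genes than its partners. Correlations of log2 values across genes were 0.843 between JPX-0700 replicates 1 and 2 but 0.611 and 0.623 between either of them and replicate 3. They were 0.886 and 0.684 to 0.686 for the corresponding JPX-0750 libraries, and 0.869 to 0.941 among DMSO libraries.

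**Figure D1:**
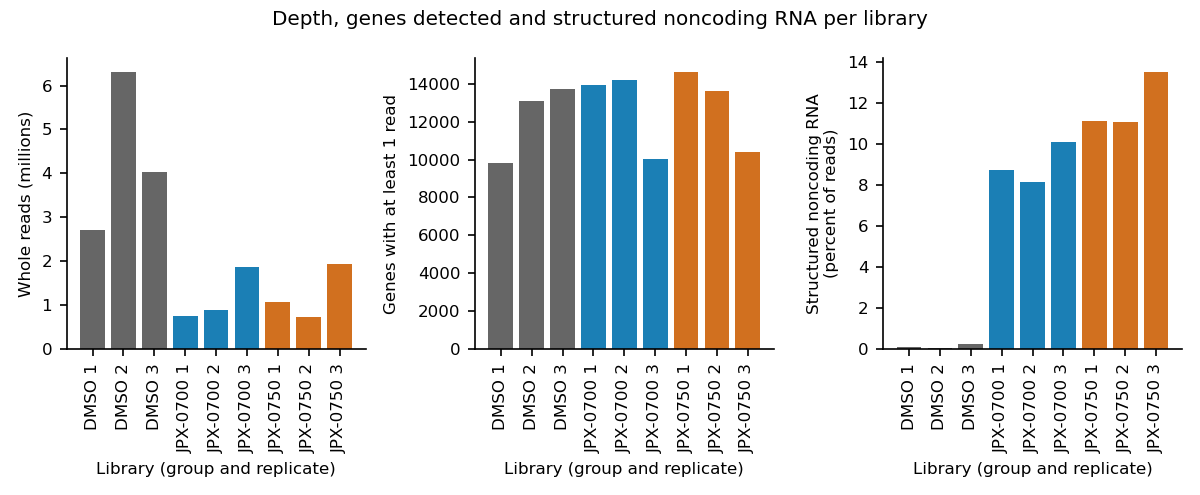
Bars give, for each of the 9 libraries, the whole reads (axis in units of 1e+06), the number of genes with at least 1 read, and the percent of reads on structured noncoding RNAs, coloured by group. Treated libraries held 8.15 to 13.5% structured noncoding RNA, DMSO libraries at most 0.235%.

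The shares of 3 read classes in every treated library lay outside the range of the DMSO libraries. Structured noncoding RNAs (small nuclear, nucleolar, Y, vault and related RNAs) took 0.119% ± 0.102 (SD, n = 3) of reads with DMSO, 8.98% ± 0.994 with JPX-0700 and 11.9% ± 1.38 with JPX-0750. Whether DMSO and treated libraries were prepared together, and the quality of their RNA, are not given in the sources used here. Protein-coding genes took 98.2% ± 0.194, 81.4% ± 1.32 and 78.7% ± 2.12, and MALAT1, a nuclear noncoding RNA, took 0.387% ± 0.191, 6.03% ± 2.18 and 6.15% ± 2.72. For the structured share of either compound against DMSO the two-sided exact permutation test gave p = 0.1, the smallest it can give with n = 3 per group. Ribosomal protein genes took 17.4% ± 3.07, 18.1% ± 4.03 and 16.2% ± 1.11 of reads.

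The genes of the proteins named as targets came first. STAT3 (chromosome 17, 42313324 to 42388442 in GRCh38) had a normalised count of 165 ± 106 (SD, n = 3) with DMSO, 144 ± 97.5 with JPX-0700 and 160 ± 124 with JPX-0750. STAT5A (chromosome 17, 42287439 to 42311943) had 75.1 ± 32.6, 53.2 ± 35.1 and 33.4 ± 26.2. STAT5B (chromosome 17, 42199177 to 42288370) had 59.4 ± 11.6, 42.9 ± 29.97 and 42.5 ± 43.2. Against DMSO the log2 fold changes of STAT3, STAT5A and STAT5B were -0.26 ± 0.85 (SE), -0.61 ± 1.12 and -0.73 ± 1.43 with JPX-0700, with adjusted p = 0.891, 0.790 and 0.804. With JPX-0750 they were -0.26 ± 0.85, -1.70 ± 1.12 and -1.95 ± 1.43, with adjusted p = 0.921, 0.524 and 0.566. With 1 library left out these ran from -0.89 to 0.60, -2.33 to -0.53 and -3.20 to 0.02. The JPX-0700 values ran from -0.78 to 0.39, -1.10 to -0.13 and -1.25 to -0.09. No difference was detectable at this depth, which was 27 to 131 reads per gene in the treated groups, and transcript levels do not measure degradation of the proteins. The annotated spans of STAT5A and STAT5B overlap at their ends.

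The first comparison asked what changed in the leukaemia cells with JPX-0700. The co-chaperone transcripts BAG3 and DNAJB1 rose 54.1-fold and 34.3-fold over DMSO (log2 fold changes 5.76 ± 0.47 and 5.10 ± 0.43 SE, n = 3 per group). PPP1R15A, whose product directs the phosphatase that restores translation after stress, rose 69.5-fold (6.12 ± 0.47), and JUN, a subunit of the transcription factor AP-1, rose 674-fold (9.40 ± 0.85). MCM2, a subunit of the replicative helicase, fell by 3.27 on the log2 scale (± 0.65), from 509 ± 148 (SD) to 50.6 ± 8.14 normalised counts, and SRGN, the proteoglycan of secretory granules, fell by 2.10 (± 0.47). Without DMSO replicate 1 or 2 the log2 fold change of JUN was 8.04 or 10.33.

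Of 12301 genes tested in limma, 649 rose and 61 fell with JPX-0700. The JPX-0700 libraries lay wholly above or below the DMSO libraries in 26.9% of the genes tested, where chance gives 10%, and in 709 of the 710, which the test selects for such separation. Scaling each library to the same total moved the median log2 fold change of all genes from 0.14 to -0.52 and gave 378 higher and 279 lower. Without the 3 libraries with the fewest genes, an alternative chosen after seeing the data, 2158 rose and 443 fell, with 654 of the 710 among them, and without DMSO replicate 1 or 2 the total was 422 or 390. Of the genes named below, CCNE2, PSAP, RPL41, RPL38, ITGB2 and HSP90AA1 lost their calls without those 3 libraries (adjusted p = 0.0557, 0.0838, 0.0688, 0.119, 0.0962 and 0.119).

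The fixed lists of heat shock, ATF4 response, immediate early and p53 target genes lay above other genes with JPX-0700, with part of their members past the test. Of 27 measured heat shock genes 11 rose and 0 fell (15 and 0 adjusted over the list alone), among them HSPB1, a small heat shock protein (20.8-fold), and HSPH1, a nucleotide exchange factor for HSP70 (8.43-fold). Of 43 genes of the ATF4 amino acid response 10 rose and 0 fell (13 and 0 adjusted over the list alone), among them the transcription factor DDIT3 (84.5-fold) and the cystine transporter SLC7A11 (46.1-fold). The stress cytokine GDF15 had 1 read over the DMSO group, a ratio of 1855 with a 95% counting interval of 330 to 73523. Of 28 immediate early and ERK feedback genes 8 rose and 0 fell (10 and 0 adjusted over the list alone), among them IER5 (18.1-fold), the phosphatase DUSP1 (130-fold) and FOSB, which had 3 DMSO reads and a ratio of 869 (295 to 4233). Of 28 p53 targets 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them GADD45A (27.6-fold), the p53 ligase MDM2 (9.53-fold) and the BH3-only gene PMAIP1 (12.8-fold). Camera placed these lists above other genes with adjusted p = 1.03e-05, 0.000593, 0.00658 and 0.00658 in that order, and each had adjusted p = 0.0671 with an estimated correlation. Log2 fold changes moved without single libraries. They were 6.40 for DDIT3 (5.13 without DMSO replicate 1 and 7.20 without DMSO replicate 3), 4.18 for IER5 (4.87 and 3.45 without the same libraries), 4.38 for HSPB1 (5.10 and 3.67 without JPX-0700 replicates 2 and 3) and 7.92 for FOSB (7.28 without JPX-0700 replicate 3).

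Of 21 NF-kB targets and cytokines 5 rose and 0 fell with JPX-0700 (6 and 0 adjusted over the list alone). They included NFKBIZ (49.3-fold), the chemokine CXCL8 (77.6-fold), the apoptosis inhibitor BIRC3 (55.7-fold) and the NF-kB inhibitor NFKBIA (3.78-fold, adjusted p = 0.0127, and 0.0517 without DMSO replicate 3). The log2 fold change of CXCL8, 6.28, was 6.99 without JPX-0700 replicate 2 and 5.23 without replicate 3. The list had adjusted p = 0.00658, adjusted p = 0.0730 with an estimated correlation, and 0.0989 without the 3 libraries with the fewest genes. Its alternatives ranged from 0.000611, by fry for a net rise or fall, to 0.0989. In the same libraries structured noncoding RNA took 8.98% of reads against 0.119% with DMSO, and mean depth was 1161260 reads against 4347420, for this and every other group of genes.

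Lists of replication, mitosis and growth lay below other genes with JPX-0700. Of 45 G1/S and DNA replication genes 1 rose and 4 fell (1 and 5 adjusted over the list alone), with adjusted p = 1.96e-05 for the list and adjusted p = 0.0671 with an estimated correlation. MCM2 was joined by RRM1, a subunit of ribonucleotide reductase, which fell by 1.99, and by the flap endonuclease FEN1, which fell by 2.44, while cyclin E2 (CCNE2) rose 8.03-fold. The RRM1 call was lost without DMSO replicate 1 (adjusted p = 0.152), that of FEN1 without DMSO replicate 1 or 2 or JPX-0700 replicate 1 (0.149, 0.16 and 0.0684), and that of CCNE2 without DMSO replicate 1 or 2 or JPX-0700 replicate 3 (0.114, 0.109 and 0.0759). The log2 fold change of CCNE2, 3.01, was 3.67 without DMSO replicate 3 and 2.4 without JPX-0700 replicate 3. Of 45 G2/M and mitosis genes 0 rose and 0 fell by either adjustment, and the list had adjusted p = 0.00658, or adjusted p = 0.302 with an estimated correlation. Of 43 MYC targets and ribosome biogenesis genes 1 rose and 0 fell (0 and 0 adjusted over the list alone), against the direction of the list, whose adjusted p was 0.0198 (adjusted p = 0.0874 with an estimated correlation, and 0.176 and 0.0793 without JPX-0700 replicate 1 or 2). That gene was WDR74, whose span also holds the small nuclear RNA gene RNU2-2 (5.10-fold), and its call was lost in 6 of the 9 fits without 1 library (adjusted p = 0.0561 to 0.176), those without DMSO replicates 1 to 3, JPX-0700 replicate 3 or JPX-0750 replicates 1 and 2. Its log2 fold change of 2.35 was 1.75 without JPX-0700 replicate 3.

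Other called lists held few called members. Of 16 granule and progenitor genes SRGN fell (1 rose and 3 fell adjusted over the list alone), with adjusted p = 0.0114 for the list and adjusted p = 0.0874 with an estimated correlation, and the SRGN call was lost without JPX-0700 replicate 3 (adjusted p = 0.0571). Of 37 lysosome and autophagy genes the saposin precursor PSAP fell by 2.78 (0 and 1 adjusted over the list alone), a call lost without DMSO replicate 1 or 2 or JPX-0700 replicate 1 or 3 (adjusted p = 0.133, 0.0925, 0.0793 and 0.0516). Its log2 fold change was -2.18 without JPX-0700 replicate 1 and -3.41 without replicate 2. The lysosome list lay below other genes with adjusted p = 0.0159 (adjusted p = 0.247 with an estimated correlation, and 0.0567 and 0.0793 without JPX-0700 replicate 1 or 2). The 57 nuclear oxidative phosphorylation genes and the 16 fatty acid synthesis genes held 0 called members and lay below other genes with adjusted p = 0.0274 and 0.0371 (adjusted p = 0.724 and 0.166 with an estimated correlation). The former lost its call without DMSO replicate 2 or JPX-0700 replicate 1 or 2 (adjusted p = 0.142, 0.289 and 0.626), the latter without DMSO replicate 1 or those same treated libraries (0.0548, 0.176 and 0.0664). With a mean of at least 50 required they had 0.0528 and 0.237, and at equal depth the fatty acid list had 0.0528. Fry tests a list for a net rise or fall and not against other genes. By it the lists of G2/M, ribosomal protein, oxidative phosphorylation, fatty acid and lysosome genes did not pass (adjusted p = 0.169, 0.217, 0.569, 0.0835 and 0.154). By its mixed form, which allows members to move in either direction, fatty acid, lysosome and ribosomal protein genes had adjusted p = 0.00396, 0.0108 and 0.0489. G2/M and oxidative phosphorylation genes had 0.130 and 0.293 by that form. Of 75 cytosolic ribosomal proteins 4 rose and 0 fell, as many adjusted over the list alone: RPL23A (6.60-fold), whose span holds 4 nucleolar RNA genes, RPL41 (6.01-fold), RPS25 (3.84-fold) and RPL38 (3.09-fold). The ribosomal list lay above other genes with adjusted p = 0.0114 (adjusted p = 0.724 with an estimated correlation), but below them, with adjusted p = 0.679, after quantile normalization and, with 0.843, without JPX-0700 replicate 3. Total-sum scaling gave adjusted p = 0.450, TMM 0.0546 and the fit without DMSO replicate 3 0.142, and RPL38 lost its call without DMSO replicate 1 or JPX-0700 replicate 1 or 3 (0.155, 0.0806 and 0.0732).

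By camera the lists named for the targets were not called with JPX-0700. Their median log2 fold changes were -0.96 (STAT5) and -0.26 (STAT3), and fry for a net rise or fall gave adjusted p = 0.569 for both. The mixed form of fry, which allows members to move in either direction, gave adjusted p = 0.00262 and 1.44e-08. Other uncalled lists passed that form too, such as NRF2 (1.64e-06), and it gives no direction. Of 18 STAT5 target genes 0 rose and 0 fell by either adjustment (list adjusted p = 0.256), and those with the smallest p were the interleukin 2 receptor gene IL2RA (log2 fold change 4.81 ± 1.48 SE, adjusted p = 0.0670), CCND3 (-1.68 ± 0.57, 0.101), PIM2 (-2.17 ± 0.75, 0.11) and MYC (-2.11 ± 0.90, 0.201). With 1 library left out they ran from 4.21 to 5.28, -2.22 to -1.35, -2.87 to -1.75 and -2.80 to -1.26. Of 21 STAT3 target genes 2 rose and 0 fell (4 and 0 adjusted over the list alone), with adjusted p = 0.751 for the list. These were FOS (11.3-fold, adjusted p = 0.000498) and VEGFA (4.84-fold, 0.0491, over its alternatives 0.00413 to 0.209), whose call was lost without any 1 library but JPX-0700 replicate 3 (0.0556 to 0.209), where its log2 fold change rose from 2.27 to 2.87. JUNB and CEBPD had log2 fold changes of 1.98 ± 0.59 and 1.62 ± 0.55 (adjusted p = 0.0603 and 0.101).

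The remaining lists did not pass with JPX-0700 in the main test, before any alternative setting. The NRF2 antioxidant response (31 genes, adjusted p = 0.555) held 2 genes that rose, SLC7A11 and the haem oxygenase HMOX1 (135-fold from 4 DMSO reads), and 1 that fell, TALDO1 (5.29-fold lower), the latter call being lost without DMSO replicate 1 or 2 (adjusted p = 0.0547 and 0.0925). The log2 fold change of HMOX1, 7.08, was 6.38 and 7.83 without JPX-0700 replicates 2 and 3, and that of TALDO1 was -1.71 without JPX-0700 replicate 3. Called members of further lists, named after their values were seen, were PMAIP1 and BBC3 in the BCL2 family (16 genes, list adjusted p = 0.452), XAF1 and TRIM22 in the type I interferon response (33, 0.555), P4HA1 and VEGFA in glycolysis and hypoxia (32, 0.0536) and PSMC1 among proteasome subunits (35, 0.168), all of which rose. The calls of BBC3, XAF1, TRIM22, P4HA1 and PSMC1 were each lost without 3 to 7 single libraries, DMSO replicate 2 among them for each (adjusted p = 0.0507, 0.0799, 0.137, 0.0991 and 0.116). The others were DMSO replicates 1 and 3, JPX-0700 replicate 3 and JPX-0750 replicates 1 to 3 for BBC3 (0.0600 to 0.238), DMSO replicate 1 and JPX-0700 replicate 1 for XAF1 (0.0849 and 0.0519), DMSO replicate 3 and JPX-0700 replicate 3 for TRIM22 (0.0630 and 0.0643), DMSO replicates 1 and 3, JPX-0700 replicate 1 and JPX-0750 replicate 2 for P4HA1 (0.0596 to 0.130), and JPX-0700 replicates 2 and 3 for PSMC1 (0.0598 and 0.0565).

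Some of these lists passed under other settings, all in the same direction. The glycolysis and hypoxia list lay below other genes in 14 of 25 alternatives, with adjusted p = 0.0199 under total-sum scaling, 0.0371 after quantile normalization and 0.0427 with TMM (0.00786 to 0.214 over all 25). The proteasome list did so in 5, with 0.0168 under total-sum scaling, 0.0423 after quantile normalization, 0.0296 by voom, 0.00104 without JPX-0700 replicate 3 and 0.00191 without the 3 libraries with the fewest genes (up to 0.757). ER chaperones lay below other genes with no filter, total-sum scaling or voom (0.0231, 0.0265 and 0.0161, up to 0.365), cholesterol biosynthesis with no filter or without DMSO replicate 3 (0.0189 and 0.0301, up to 0.612), and STAT and JAK components by voom (0.0356, up to 0.667). T and NK cell markers lay above other genes with no filter (0.0367, up to 0.863).

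Of 35 monocyte and macrophage genes 1 rose and 1 fell with JPX-0700 (3 and 2 adjusted over the list alone), with adjusted p = 0.751 for the list. The integrin gene ITGB2, named after its values were seen, fell by 3.53, a call lost without DMSO replicate 1 or 2, JPX-0700 replicate 3 or JPX-0750 replicate 3 (adjusted p = 0.127, 0.0756, 0.0694 and 0.0605). The log2 fold change of ITGB2 was -4.20 without DMSO replicate 3, -4.44 and -2.22 without JPX-0700 replicates 2 and 3, and -1.68 without the 3 libraries with the fewest genes. The other lists held 0 called members. Their adjusted p was 0.0751 for cholesterol biosynthesis, 0.0919 for ER chaperones, 0.147 for STAT and JAK components, 0.452 for the MLL fusion programme, 0.555 for metallothioneins, 0.930 for negative regulators of cytokine signalling and 0.998 for MHC class II. Markers of other cell types gave 0.555 for erythroid, 0.555 for epithelial, 0.602 for T and NK and 0.691 for B cells. Median, mean and test differed in sign for 6 of the 32 lists, all among the 19 not called (STAT3 targets, MHC class II, NRF2, monocyte, negative regulators and B cell markers).

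The largest rises with JPX-0700 were in structured noncoding RNAs. RNY4 and RNY5, Y RNAs, rose by log2 fold changes of 12.41 ± 0.74 and 12.27 ± 0.80 (SE, n = 3), RN7SK, the RNA that holds the elongation factor P-TEFb inactive, by 11.96 ± 0.55, and the nucleolar RNAs SNORD46 and SNORD3A by 11.66 ± 0.48 and 11.37 ± 0.65. SNORD14E had 2 DMSO reads and a ratio of 12572 (95% counting interval 3478 to 103848). These RNAs come from families of many similar copies and SNORD14E lies inside the protein-coding gene HSPA8, so the assignment of their reads is uncertain. Without DMSO replicate 3 or JPX-0700 replicate 3 RNY4 had 13.03 or 11.44, and without JPX-0700 replicates 2 or 3 RNY5 had 13.18 or 11.31. RN7SK had 11.28 or 12.59 without DMSO replicates 1 or 3, and SNORD3A had 10.51 or 10.71 without DMSO replicate 1 or JPX-0700 replicate 3.

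The largest falls with JPX-0700 were in B3GNT7, a glycosyltransferase (log2 fold change -5.21 ± 1.19), CGREF1 (-5.19 ± 1.37), DCANP1 (-5.09 ± 1.19), the heparan sulphate polymerase EXT2 (-4.91 ± 1.33), the chemokine receptor CCR2 (-4.80 ± 1.26) and CCZ1 (-4.65 ± 1.33), a gene with a near-identical copy. CGREF1 and EXT2 had 1 read and CCZ1 had 3 reads over the JPX-0700 group, ratios of 0.0169 (0.000427 to 0.0949), 0.0230 (0.00058 to 0.129) and 0.0368 (0.00757 to 0.108). B3GNT7 lost its call without DMSO replicate 1 or 2 (adjusted p = 0.0535 and 0.121) and DCANP1 without DMSO replicate 2 or 3 (0.125 and 0.0696), while CGREF1, EXT2, CCR2 and CCZ1 lost theirs without any 1 of the DMSO libraries and without 2 to 4 of the treated ones (0.0518 to 0.261). Without JPX-0700 replicate 3 the log2 fold changes of B3GNT7, DCANP1, CCR2 and CCZ1 were -3.66, -3.65, -2.88 and -3.72. Without replicate 1 those of B3GNT7, CGREF1, CCR2 and CCZ1 were -6.18, -6.02, -5.94 and -5.39, and without replicate 2 those of B3GNT7, DCANP1, EXT2 and CCR2 were -5.80, -6.03, -5.65 and -5.57. CCZ1 had -4.04 without DMSO replicate 1 and -5.24 without DMSO replicate 3.

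The second comparison asked the same of JPX-0750. JUN rose 266-fold over DMSO (log2 fold change 8.06 ± 0.85 SE, n = 3 per group), PPP1R15A 45.0-fold (5.49 ± 0.47), BAG3 27.8-fold (4.80 ± 0.47) and DNAJB1 21.7-fold (4.44 ± 0.43). GADD45A, a stress gene activated by p53, rose 30.3-fold (4.92 ± 0.61). Without DMSO replicate 1 or 2 the log2 fold change of JUN was 6.70 or 8.99, and without JPX-0750 replicate 3 that of GADD45A was 5.52. BIRC5, the mitotic protein survivin, fell by 2.31 on the log2 scale (± 0.55), from 435 ± 48.4 (SD) to 89.3 ± 25.8 normalised counts.

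Of 12301 genes tested in limma, 480 rose and 9 fell with JPX-0750. The JPX-0750 libraries lay wholly above or below the DMSO libraries in 28.9% of the genes tested, where chance gives 10%, and in 487 of the 489, which the test selects for such separation. Total-sum scaling moved the median log2 fold change of all genes from 0.26 to -0.25 and gave 304 higher and 57 lower. Without the 3 libraries with the fewest genes 2184 rose and 375 fell, with 484 of the 489 among them. COLGALT1 and HSP90AA1, named below, lost their calls in that fit (adjusted p = 0.0695 and 0.0955). The count was 307 without DMSO replicate 2, 1096 without JPX-0700 replicate 3, and 254 and 270 without JPX-0750 replicates 1 and 2.

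The lists of p53 targets, heat shock, ATF4 response and immediate early genes also lay above other genes with JPX-0750, with part of their members past the test. Of 28 p53 targets 6 rose and 0 fell (14 and 0 adjusted over the list alone), among them PMAIP1 (14.0-fold) and MDM2 (8.47-fold). Of 27 heat shock genes 9 rose and 0 fell (14 and 0 adjusted over the list alone), among them the HSP110 gene HSPA4L (14.0-fold) and HSPH1 (6.34-fold). Of 43 ATF4 response genes 7 rose and 0 fell (13 and 0 adjusted over the list alone), among them DDIT3 (80.4-fold), SLC7A11 (27.2-fold) and GDF15, with 1 DMSO read and a ratio of 1545 (275 to 61216). Of 28 immediate early genes 8 rose and 0 fell (11 and 0 adjusted over the list alone), among them FOS (14.4-fold), IER5 (21.5-fold) and FOSB, with a ratio of 545 (185 to 2657). Camera placed these 4 lists above other genes with adjusted p = 2.18e-07, 8.04e-06, 8.76e-05 and 0.000289 in that order, and adjusted p = 0.0219, 0.0383, 0.0344 and 0.0354 with an estimated correlation. Without DMSO replicate 1 the log2 fold change of DDIT3, 6.33, was 5.05 and that of IER5, 4.42, was 5.12. Without DMSO replicate 3 they were 7.13 and 3.70.

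Of 21 NF-kB targets and cytokines 4 rose and 0 fell with JPX-0750 (6 and 0 adjusted over the list alone), namely NFKBIZ (53.2-fold), NFKBIA (5.36-fold), CXCL8 (42.3-fold) and BIRC3 (31.7-fold). The list had adjusted p = 0.00371, adjusted p = 0.0459 with an estimated correlation and 0.179 without the 3 libraries with the fewest genes, over a range of 0.000501 to 0.179 for its alternatives, fry with its other null among them. CXCL8 lost its call without JPX-0750 replicate 1 or 3 (adjusted p = 0.0986 and 0.0573), and BIRC3 without DMSO replicate 2 or JPX-0750 replicate 1 or 2 (0.0635, 0.132 and 0.140). In the JPX-0750 libraries structured noncoding RNA took 11.9% of reads against 0.119% with DMSO, and mean depth was 1245740 reads against 4347420, for this and every other group of genes.

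Mitotic and replication genes lay below other genes as lists with JPX-0750, with few single genes past the test. Of 45 G2/M and mitosis genes 0 rose and 1 fell, BIRC5 (0 and 3 adjusted over the list alone), with adjusted p = 9.73e-09 for the list and adjusted p = 0.0459 with an estimated correlation. Of 45 G1/S and DNA replication genes 0 rose and 0 fell by either adjustment (adjusted p = 1.27e-06, and adjusted p = 0.0354 with an estimated correlation). The 43 MYC targets and ribosome biogenesis genes and the 57 nuclear oxidative phosphorylation genes held 0 called members by either adjustment, with adjusted p = 0.00233 and 1.73e-05 (adjusted p = 0.0383 and 0.401 with an estimated correlation). Of 16 granule and progenitor genes SRGN fell by 1.82 (0 and 2 adjusted over the list alone), with adjusted p = 0.00229 for the list (adjusted p = 0.0459 with an estimated correlation). Of 37 lysosome and autophagy genes LAMP2, a lysosomal membrane protein, fell by 1.96 (0 and 1 adjusted over the list alone), with adjusted p = 0.0133 (adjusted p = 0.240 with an estimated correlation, and 0.0639 without JPX-0750 replicate 1).

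The lists of proteasome subunits and of glycolysis and hypoxia also lay below other genes with JPX-0750. The 35 proteasome genes held 0 called members, with adjusted p = 0.0244 (adjusted p = 0.480 with an estimated correlation, 0.119 after quantile normalization, and 0.252 and 0.184 without JPX-0750 replicate 1 or 2). Of 32 glycolysis and hypoxia genes the enolase ENO1 fell by 1.49 (3 rose and 2 fell adjusted over the list alone), with adjusted p = 0.0450 (adjusted p = 0.144 with an estimated correlation). That list lost its call without DMSO replicate 1, JPX-0700 replicate 2 or JPX-0750 replicate 1 or 2 (0.209, 0.0504, 0.265 and 0.123). It also lost it with no filter on low values (0.0560), after quantile normalization (0.127), with only the groups compared (0.0603), with the replicate block (0.0763) and without structured noncoding RNAs (0.0604). By fry, which tests for a net rise or fall of the list, those of proteasome, glycolysis, oxidative phosphorylation, granule and lysosome genes did not pass with JPX-0750 (adjusted p = 0.561, 0.481, 0.409, 0.0605 and 0.463). The SRGN call was lost without any of the DMSO libraries, JPX-0700 replicate 3 or JPX-0750 replicate 1 or 2 (adjusted p = 0.0716 to 0.279), and its log2 fold change was -2.43 without JPX-0750 replicate 3. The ENO1 call was lost without any 1 library but JPX-0700 replicate 3 and JPX-0750 replicate 3 (0.0527 to 0.30).

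Of 35 monocyte and macrophage genes 2 rose and 1 fell with JPX-0750 (4 and 1 adjusted over the list alone), with adjusted p = 0.689 for the list. Among them the transcription factor KLF2 rose 37.2-fold and lysozyme, LYZ, fell by 1.93. The KLF2 call was lost without any 1 library but JPX-0700 replicate 3 (adjusted p = 0.0590 to 0.186; log2 fold change 5.22, and 5.94 without DMSO replicate 2), and that of LYZ without DMSO replicate 1 or 2 or JPX-0750 replicate 1 or 2 (0.0865, 0.158, 0.214 and 0.139).

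STAT target lists were not called by camera with JPX-0750 either. Their median log2 fold changes were -0.60 (STAT5) and 0.21 (STAT3), and fry for a net rise or fall gave adjusted p = 0.566 and 0.409. Its mixed form, for members moving in either direction, gave adjusted p = 0.0535 and 3.98e-07. Of 18 STAT5 target genes 0 rose and 0 fell by either adjustment (list adjusted p = 0.103), and those with the smallest p were the feedback inhibitors SOCS1 (log2 fold change 3.98 ± 1.49 SE, adjusted p = 0.189) and CISH (-2.37 ± 1.14, 0.365), then BCL6 (3.01 ± 1.48, 0.372) and CCND2 (-1.29 ± 0.64, 0.378). With 1 library left out they ran from 3.58 to 4.77, -3.18 to -0.79, 2.00 to 4.05 and -1.53 to -0.99. Of 21 STAT3 target genes 1 rose, FOS, and 1 fell, BIRC5 (2 and 1 adjusted over the list alone), with adjusted p = 0.983 for the list. VEGFA and JUNB had log2 fold changes of 2.22 ± 0.66 and 1.56 ± 0.59 (adjusted p = 0.0703 and 0.200).

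The remaining lists did not pass with JPX-0750 in the main test. Cytosolic ribosomal proteins (RPS25 and RPL23A), the NRF2 response (SLC7A11 and HMOX1) and the BCL2 family (PMAIP1 and BBC3) held 2 genes each that rose and 0 that fell (list adjusted p = 0.739, 0.708 and 0.630), named here after their values were seen. The RPS25 call was lost without DMSO replicate 1 or JPX-0750 replicate 1 or 2 (adjusted p = 0.116, 0.11 and 0.0745), that of RPL23A without DMSO replicate 1 or 2 or the same JPX-0750 libraries (0.107, 0.0596, 0.136 and 0.0777), and that of BBC3 without any 1 of the DMSO or JPX-0750 libraries (0.0501 to 0.254). The others held 0 called members, with adjusted p of 0.103 for fatty acid synthesis (0.0139 without JPX-0750 replicate 3 and 0.0316 without the 3 libraries with the fewest genes, up to 0.559), 0.214 for ER chaperones, 0.214 for STAT and JAK components, 0.309 for the MLL fusion programme, 0.602 for cholesterol biosynthesis, 0.630 for MHC class II, 0.763 for negative regulators of cytokine signalling, 0.967 for the type I interferon response and 0.983 for metallothioneins. Markers of other cell types gave 0.366 for B, 0.668 for erythroid, 0.775 for epithelial and 0.796 for T and NK cells. Median, mean and test differed in sign for 7 of the 32 lists, all among the 19 not called (interferon, ER chaperones, NRF2, BCL2 family, cholesterol, monocyte and epithelial).

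The largest rises with JPX-0750 were again structured noncoding RNAs. RNY4, RNY5, SNORD46 and SNORD83A had log2 fold changes of 13.21 ± 0.74, 13.01 ± 0.80, 12.26 ± 0.48 and 11.57 ± 0.56 (SE, n = 3). Without DMSO replicate 3 RNY4 had 13.84, and without JPX-0750 replicate 3 RNY4 had 12.62, RNY5 had 11.98 and VTRNA1-1 moved from 11.62 to 12.22. The vault RNA VTRNA1-1 had 3 DMSO reads and a ratio of 7016 (95% counting interval 2399 to 34033), and RNU12, a small nuclear RNA of the minor spliceosome, had 0 DMSO reads and was at least 5409-fold higher against a floor of 3 reads over the group. The largest falls were in COLGALT1, a collagen galactosyltransferase (log2 fold change -2.96 ± 0.64), BIRC5, the tetraspanin CD81 (-2.19 ± 0.52), the splicing factor TXNL4A (-2.03 ± 0.54), the RNA-binding protein LSM4 (-2.02 ± 0.52) and LAMP2 (-1.96 ± 0.48). Each of these 6 lost its call without DMSO replicate 2 (adjusted p = 0.0988 to 0.236) and without 2 to 5 further libraries among DMSO replicates 1 and 3 and JPX-0750 replicates 1 to 3 (0.0541 to 0.184).

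**Figure D2:**
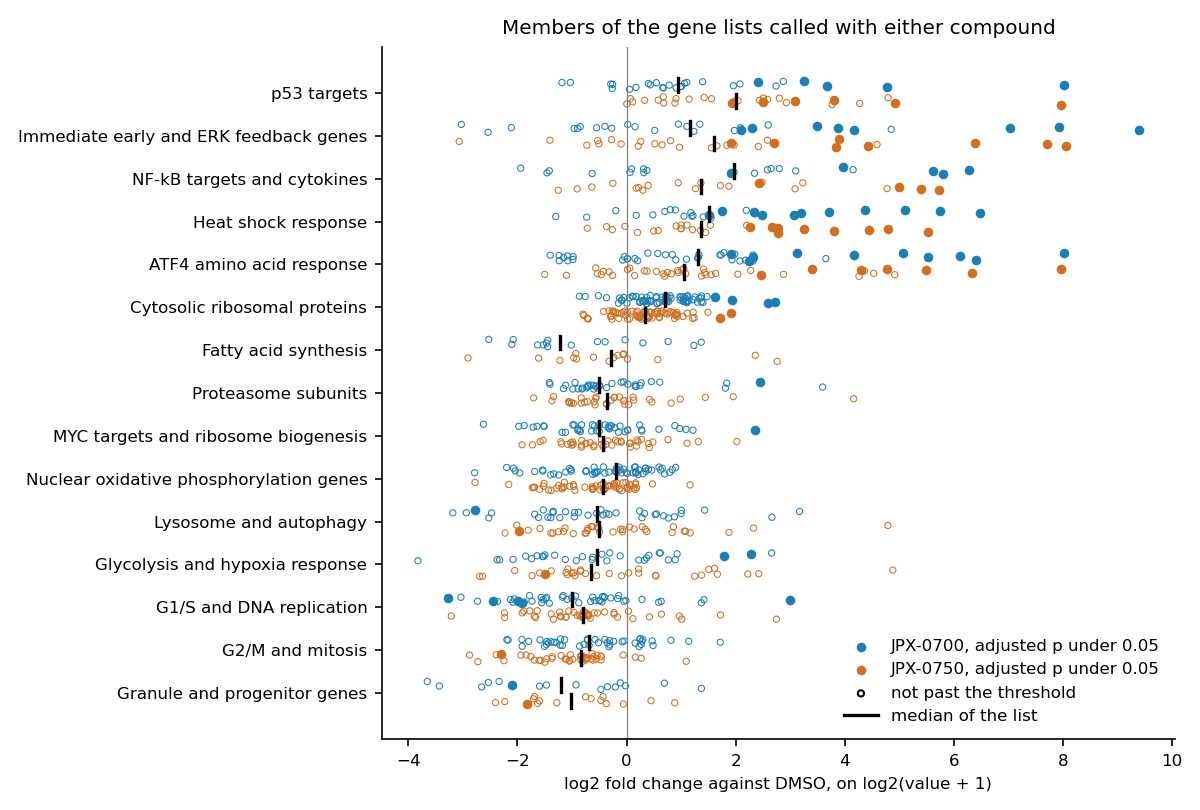
Points give the log2 fold change against DMSO (horizontal axis) of each member of the lists called with either compound, filled where adjusted p was under 0.05, with black lines at list medians. With JPX-0750 the median of the p53 targets lay at 2.01 and that of the G2/M genes at -0.84.

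**Figure D3:**
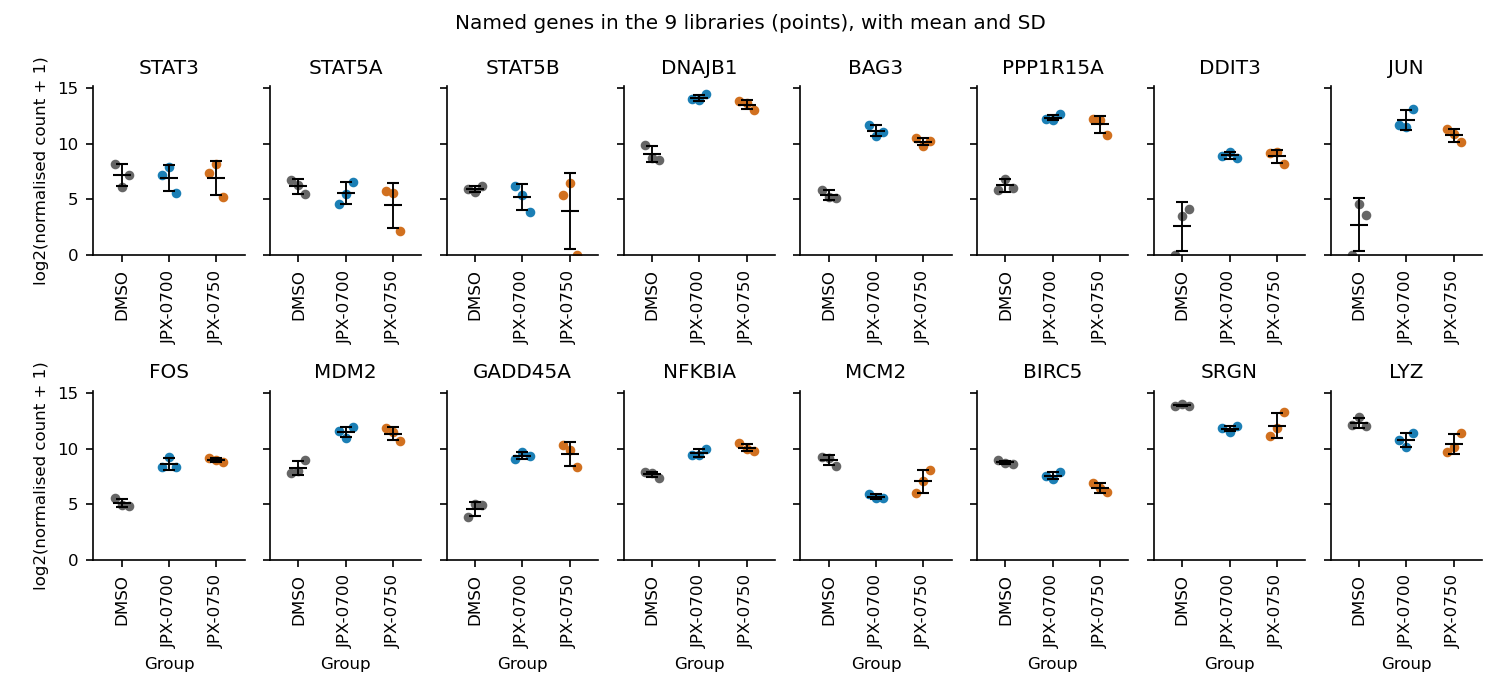
Points give log2(normalised count + 1) in each of the 3 libraries per group for 16 named genes, with mean and SD. DNAJB1, BAG3, PPP1R15A, DDIT3, JUN, FOS, MDM2, GADD45A and NFKBIA lay above DMSO in all 6 treated libraries, and the STAT genes overlapped between groups.

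The next comparison asked how far the compounds changed the same genes. With both, 415 genes rose, 3 fell and 0 moved in opposite directions, where independent lists of these sizes would share 25.3 and 0.0446. Of the 418, 131 were structured noncoding RNAs and 287 were other genes, among them JUN, FOS, FOSB, IER5, DNAJB1, BAG3, HSPH1, PPP1R15A, DDIT3, SLC7A11, GADD45A, MDM2, PMAIP1, NFKBIZ and NFKBIA. The 3 that fell with both were SRGN, COLGALT1 and CD81. Across all genes tested, which are not independent replicates, log2 fold changes had r = 0.788 and Spearman's rho = 0.726, and 76.3% had the same sign. Because both compounds were compared with the same DMSO libraries, 20 simulations of unchanged groups gave r = 0.499 on average (0.479 to 0.515), 66.7% with the same sign and 0 shared calls. Their noise was drawn independently for each gene, without deviations that many genes of a library share. It also left out the correlations of 0.129, 0.171 and 0.190 between JPX-0700 and JPX-0750 libraries of the same number. The simulated ranges are therefore likely too narrow to judge r and the share of signs by. The counts that rose and fell with both were 276 and 43 with total-sum scaling, 407 and 40 after quantile normalization and 1792 and 214 without the 3 libraries with the fewest genes, so the few shared falls depended on the scaling and on those libraries. The shared count was 2006 without the 3 libraries with the fewest genes, 237 without structured noncoding RNAs, 758 without JPX-0700 replicate 3, and 251 and 262 without JPX-0750 replicates 1 and 2.

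**Figure D4:**
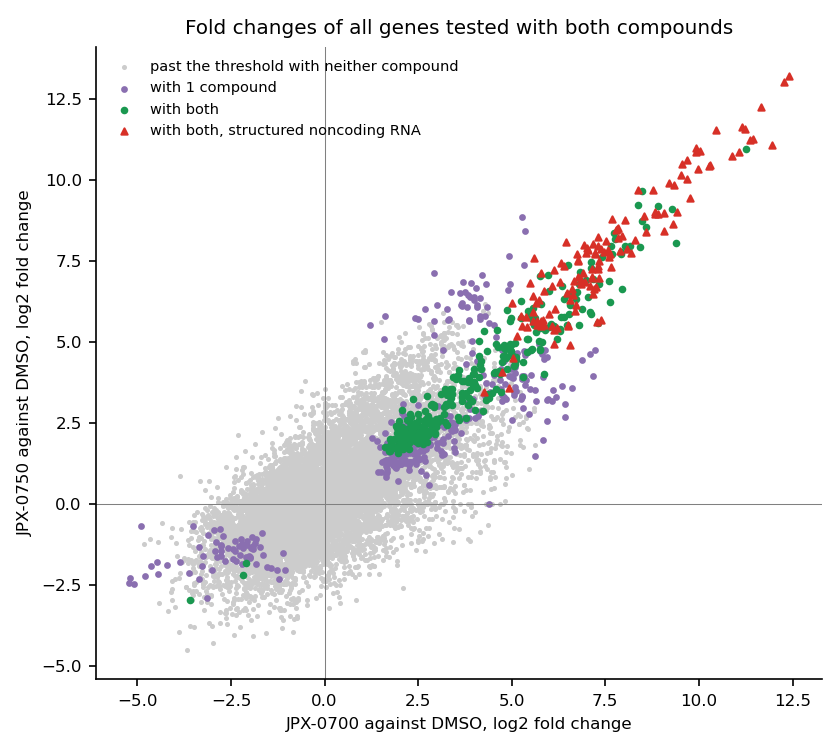
Each point is 1 of 12301 genes, with its log2 fold change against DMSO for JPX-0700 (horizontal) and JPX-0750 (vertical), coloured by whether it passed with neither, 1 or both compounds. The 131 structured noncoding RNAs past the threshold with both are shown as triangles.

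The last comparison set JPX-0750 against JPX-0700 directly, at doses the labels do not give. As lists, p53 targets lay higher with JPX-0750, by a mean of 0.85 on the log2 scale (95% interval 0.21 to 1.49, camera adjusted p = 0.00871). G2/M and mitosis genes lay lower, by a mean difference of -0.45 (-1.13 to 0.23, adjusted p = 0.00217), as did cytosolic ribosomal proteins, by -0.34 (-1.10 to 0.43, adjusted p = 0.00211). The 3 lists had adjusted p = 0.296, 0.929 and 0.929 with an estimated correlation, and 0 of their members passed by the count over all genes. The 3 lists lost their calls without single libraries. For p53 targets these were JPX-0700 replicates 1 and 2 and JPX-0750 replicates 1 and 3 (adjusted p = 0.166, 0.117, 0.0575 and 0.0570), and for G2/M genes JPX-0700 replicate 2 and JPX-0750 replicate 1 (0.0659 and 0.438). Ribosomal proteins had 0.0611 and 0.233 without JPX-0750 replicates 1 and 2, and lay in the opposite direction without JPX-0700 replicate 3 (0.487). They had 0.760 after quantile normalization and 0.868 without the 3 libraries with the fewest genes. By fry, which tests for a net rise or fall and not against other genes, G2/M genes and ribosomal proteins both had 0.815. In the libraries compared here structured noncoding RNA took 8.15 to 10.1% of reads with JPX-0700 and 11.1 to 13.5% with JPX-0750 (two-sided exact permutation p = 0.1, the smallest possible).

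No gene differed between the compounds in limma, with 0 past the threshold and 395 at an unadjusted p under 0.05, and voom on the recovered reads gave 0 and 540. The 95% intervals were wide, with a median half-width of 2.35 on the log2 scale, and those of 68 genes (0.553%) lay within 1 log2 unit of equality on either side. For JPX-0750 minus JPX-0700 the log2 difference and 95% interval were -0.66 (-1.55 to 0.24) for DNAJB1, -0.63 (-1.61 to 0.36) for PPP1R15A, -1.34 (-3.13 to 0.45) for JUN and -0.17 (-1.14 to 0.80) for MDM2. They were 1.36 (-0.01 to 2.72) for MCM2, -1.10 (-2.24 to 0.05) for BIRC5 and 0.28 (-0.72 to 1.27) for SRGN. The intervals of STAT3, STAT5A and STAT5B were -1.79 to 1.79, -3.46 to 1.28 and -4.24 to 1.79. Of the genes named by the rule against DMSO, those with the smallest unadjusted p were RPL41 (-1.55, -2.56 to -0.54) and EXT2 (4.24, 1.45 to 7.04), both with adjusted p = 0.848. ITGB2, named after its values were seen, differed by 2.84 ± 0.85 (SE, adjusted p = 0.848), and by 1.30 without the 3 libraries with the fewest genes. The other 29 lists had adjusted p of 0.11 or more. Without JPX-0750 replicate 3 the lists of oxidative phosphorylation, proteasome, erythroid and MHC class II genes lay lower with JPX-0750 (adjusted p = 0.000534, 0.00621, 0.0162 and 0.0450), as did oxidative phosphorylation genes without JPX-0700 replicate 1 or 2 (0.0212 and 0.00119) and interferon genes without the 3 libraries with the fewest genes (0.00210). Over their alternatives these 5 lists reached 0.938 to 0.994. STAT5 and STAT3 target genes had mean differences of -0.03 (-0.78 to 0.72) and 0.36 (-0.37 to 1.10), and median, mean and test differed in sign for 10 lists, 0 of them called.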

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

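Alternatives chosen only after the results were seen were the fits without the 3 libraries with the fewest genes, voom, equal depth, those without structured noncoding RNAs and the block over the 6 treated libraries; the edgeR and DESeq2 fits foreseen for whole counts were not run. JPX-0700 changed 710 genes and stayed within 1.5 times of that under all but 3 kinds of alternative, which gave 423 without the variance trend, 2601 without the 3 libraries and 390 to 954 with 1 library left out. For JPX-0750, 489 genes became 837 with only the groups compared, 793 by voom, 2559 without the 3 libraries, 261 without structured noncoding RNAs and 254 to 1096 with 1 library left out. The 418 shared genes became 2006, 237 and 251 to 758 under the last 3 of these. Leaving out structured RNAs removes called genes by construction; otherwise the cause was not tested. The count of 0 genes between the compounds held under every alternative run, the block over the 6 treated libraries included, in which the 3 list calls also held. Of 13 lists called with JPX-0700, 0 held with an estimated correlation and 8 by fry, and of 13 with JPX-0750, 9 and 8; of 3 between the compounds, 0 and 1, and with 1 library left out 0 to 3 of them held while 0 to 6 lists were called in all. Fry tests a list for a net rise or fall, not against other genes. Under every alternative run for lists, 0, 7 and 0 of these calls held, and the cause was not tested. The cytosolic ribosomal protein list changed direction: against DMSO with JPX-0700 its adjusted p was 0.0114 upward, but downward 0.679 after quantile normalization and 0.676 without the 3 libraries, with 4.89e-05 to 0.843 when 1 library was left out (0.843 downward, without JPX-0700 replicate 3); between the compounds it was 0.00211 downward, with 1.12e-07 to 0.487 (0.487 upward, without JPX-0700 replicate 3), and the cause was not tested. Of 46 named genes called with JPX-0700, 27 kept the call under every alternative that tested them, as did 22 of 36 with JPX-0750, and 0 changed direction while called; the minimum log2 change of 1 was applied to the counts only. Over 110 gene results there were 2296 comparisons on the same side of the threshold, 203 that lost a call and 18 that gained it. STAT3, STAT5A and STAT5B passed under no alternative run for them. Depth limits weak genes most: in the libraries with the fewest reads 1 read was worth nearly the mean of 5 required for testing. A fit with 1 library left out keeps at least 2 in each group, and that without the 3 libraries keeps 2.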

Other observations

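The genes of the next paragraphs, the gene classes and the tests of MALAT1, of the gene counts at equal depth and of the 20 top genes were chosen only after the results were seen. Outside the fixed lists, 7 genes picked after their values were seen rose with both compounds. HSPA6, a strictly inducible HSP70 gene, had 2 DMSO reads and a ratio of 11400.3 with JPX-0700 (95% counting interval 3154 to 94173) and 6749 with JPX-0750 (1866 to 55757), and HSPA2, another HSP70 gene, rose by log2 fold changes of 5.76 ± 1.06 (SE, n = 3) and 5.43 ± 1.06. HES1, a repressor downstream of Notch, rose by 8.48 ± 0.96 and 8.74 ± 0.96, RGS2, a regulator of G protein signalling, by 8.42 ± 0.86 and 7.95 ± 0.86, and PLK2, a stress-induced kinase, by 4.27 ± 0.58 and 5.35 ± 0.58. The kinase gene SGK1 had 1 DMSO read and ratios of 1465 (260 to 58140) and 1891 (337 to 74887). MAT2A, which makes S-adenosylmethionine, rose by 5.25 ± 0.93 and 6.26 ± 0.93. These 7 genes kept an adjusted p under 0.05 in every fit that left out 1 library, the highest being 0.0398 for HSPA2 with JPX-0750. They belong to a larger set picked after its values were seen, in which other calls were lost. NR4A2 had 0.0596 with JPX-0700 without DMSO replicate 1 and 0.0562 with JPX-0750 without its replicate 3. HSP90AA1 had 0.107 and 0.0622 without JPX-0700 replicate 3. NR4A3 passed with JPX-0750 only (0.0453) and reached 0.212 with 1 library left out. Without DMSO replicate 1 the log2 fold changes with JPX-0700 and JPX-0750 were 4.49 and 4.17 for HSPA2, 7.82 and 8.08 for HES1, and 3.94 and 4.95 for MAT2A. They were 6.58 and 6.26 for HSPA2 without DMSO replicate 2, and 6.03 and 7.04 for MAT2A without DMSO replicate 3. HES1 had 9.62 with JPX-0700 without its replicate 2, and 9.55 and 8.01 with JPX-0750 without its replicates 2 and 3. Without JPX-0750 replicate 3 HSPA2 had 6.28 and RGS2 8.84 with that compound, and without JPX-0700 replicate 3 HSPA6 moved from 11.25 to 10.62.

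Long noncoding RNAs also rose in part, as did replication-dependent histone mRNAs, which end without a poly(A) tail. MALAT1, whose 3′ end is also not polyadenylated, rose 27.3-fold and 23.9-fold (4.77 ± 0.52 and 4.58 ± 0.52 SE, n = 3, limma adjusted p = 7.92e-06 and 1.25e-05), and NEAT1, the RNA scaffold of paraspeckles, 33.1-fold and 21.8-fold (5.05 ± 0.43 and 4.44 ± 0.43). Of 58 replication-dependent histone genes 19 rose with JPX-0700 and 18 with JPX-0750, and 0 fell, with median log2 fold changes of 3.40 and 3.68 (adjusted p = 0.0784 and 0.0657 with an estimated correlation). HIST1H4E, for example, rose by 7.68 ± 0.87 and 7.72 ± 0.87, and by 8.45 with JPX-0750 without its replicate 3, although histone genes are near-identical and the assignment of their reads is uncertain. At a mean of 1.31 with DMSO, HIST1H4E passed the expression filter only through the treated libraries, and such genes raise the medians. Of 603 long noncoding RNAs 55 and 36 rose and 0 fell (adjusted p = 0.131 and 0.117 with an estimated correlation). Of 10908 protein-coding genes 402 rose and 61 fell with JPX-0700, and 250 rose and 9 fell with JPX-0750. As a set they lay below the other genes tested by camera (adjusted p = 4.18e-24 and 1.78e-27, and 0.0116 and 0.00833 with an estimated correlation). Their median log2 fold changes were -0.03 and 0.12, so a list can lie below other genes without a fall of its own.

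Structured noncoding RNAs were higher in all 6 treated libraries. Of 261 tested, 140 rose with JPX-0700 and 156 with JPX-0750, and 0 fell, with median log2 fold changes of 5.27 and 5.76 (6.23 and 6.72 with the DMSO group of each gene set to at least 3 reads) and adjusted p = 0.00126 and 0.000598 with an estimated correlation. With every library thinned to the same number of reads the lower of the medians was 5.37, so the pattern was also present at equal depth. Random thinning leaves the share of reads of each class unchanged on average, so this outcome was largely fixed and says no more about depth. A candidate explanation that remains is capture of RNA without a poly(A) tail in general, for which the lower median of the histone genes, 3.40, had to lie above 1. The filter on the mean over all 9 libraries weakens that test. Members near 0 with DMSO were tested only through their treated libraries, which raises both medians and leaves few that could fall. Of the 261 structured RNAs 144 had at most 3 DMSO reads and 75 had none. Loss of messenger RNA as a whole cannot be told apart from such capture, because MALAT1 lay 0.50 from the structured RNA median with JPX-0700 and 1.18 from it with JPX-0750, where within 1 for both was needed and beyond 2 for both would argue against it, and because MALAT1 lacks a poly(A) tail itself and no added standard fixes the amount of RNA. That loss alone would raise the structured RNAs by a common factor. The quartiles of their log2 fold changes were 3.03 and 7.20 with JPX-0700 and 3.62 and 7.60 with JPX-0750. This spread goes against a common factor but does not settle it, since many of them had few DMSO reads. An effect of the compounds on these RNAs is open and untested, since treatment and read class separate the same libraries, as is a difference in RNA quality or library preparation between DMSO and treated libraries, neither of which the sources used here describe.

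In each group 1 library detected fewer genes than its partners. Depth is argued against, since at equal depth DMSO replicate 1, JPX-0700 replicate 3 and JPX-0750 replicate 3 detected 84.0%, 61.2% and 71.0% of the genes of the lowest other library of their group. A few genes taking most of the counts is argued against in the treated pair, where the 20 top genes held 21.4% and 22.3% of reads against up to 23.5% and 26.1% in their partners, and cannot be told apart in DMSO replicate 1, at 12.5% against up to 12.3%. Few distinct molecules in the library and reads copied from few molecules could explain part of the pattern, but neither can be told apart from other causes: the percent of genes at 100 or more in partner libraries that had no read was 0 in DMSO replicate 1, 4.28 and 1.55 in the treated pair, and the percent of detected genes with exactly 1 read was 2.55, 15.6 and 7.81, below both partners in the DMSO and JPX-0750 libraries and above them in the JPX-0700 library. The design names no biological difference between replicates, so no biological explanation was tested.

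With either compound more genes rose than fell. Depth and the structured noncoding RNAs are argued against, since at least 93.2% of calls were higher at equal depth and at least 91.3% without those RNAs. The authors' scaling is a candidate explanation for JPX-0700, where 57.5% of calls were higher under total-sum scaling, 69.2% after quantile normalization and 80.7% with TMM, against 91.4%, although total-sum scaling shifts all genes of a library alike, so these values show that the balance depends on the scaling and not which scaling is right. For JPX-0750 the same settings gave 84.2%, 83.8% and 93.9% against 98.2%. A wider rise of transcripts with the compounds is open and untested, since the table holds no measure of RNA per cell.

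Other splits of the 6 libraries of each comparison into groups of 3 were fitted for all 10 splits, too few for a share under 0.05. Against DMSO every other split mixes DMSO and treated libraries in both groups. Any large difference between them then becomes spread within groups, so a low count was built in and does not bear on the cause. For JPX-0700 against DMSO 1 split, the real one, reached its 710 genes, and the highest other gave 0. For JPX-0750 against DMSO 1 split, the real one, reached its 489 genes, and the highest other gave 0. For JPX-0750 against JPX-0700 all 10 splits gave 0.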
